A study of Anguilla marmorata with 3 samples.

How the data were processed

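Juvenile marbled eels were taken from fresh water as controls, or after a gradual rise in salinity, and gill, kidney and intestine were dissected, per the labels' protocols. The labels give each of the 3 samples a salinity of 0, 10 or 25, printed there with a percent sign and used here as labelled, and name the 3 organs together for each sample. Whether RNA of the organs was pooled, and in which proportions, is not given in the sources used here. Per the labels' protocols, RNA was extracted with Trizol, libraries were made with an Illumina TruSeq kit, paired reads came from an Illumina HiSeq instrument, and clean reads were assembled with Trinity. DESeq is named in the submitters' processing notes without a version. The aligner, the quantifier's version and the genome build are not given in the sources used here.

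The authors deposited 1 table per library with FPKM (fragments per kilobase of locus, scaled to library size) and the bounds of an interval around each FPKM, per the file headers. Each table had 211881 rows, and each row is a locus of a gene model on a scaffold, with a median length of 142 bp, so a row is closer to an exon than to a gene. The tables held 45975 gene models, of which 32674 carried a protein entry name, with 14075 distinct names.

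The upper bound of the deposited interval was found to equal FPKM plus 2 times FPKM divided by the square root of a fragment number, which gave that number for each locus. FPKM per fragment was then fixed by locus length. From loci of at least 600 bp it gave the library totals to which FPKM was scaled, 17600708, 18325768 and 16247643 fragments for salinities 0, 10 and 25. A locus was called resolved when the recovered number, pooled over the 3 libraries, reached at least 0.9 of the number the FPKM implied, which held for 80.9% of loci above 0 in any library. Within each library, a bound of 0.95 held for 80.3%, 79.9% and 79.3% of loci above 0, and of these 96.0%, 95.2% and 95.5% gave a whole number of fragments within 0.01. Short loci carry little information. A single fragment was worth 136 FPKM in a locus of 110 bp at salinity 0 and 0.0677 FPKM in one of 1000 bp, and loci of 101 to 149 bp held 79.7%, 79.3% and 78.0% of the summed FPKM.

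The design fixed before the data were examined summed the FPKM of all rows of a gene. Because the rows turned out to be exon-sized loci, the main value was computed instead as the fragments of all resolved loci of at least 101 bp with the same entry name, divided by their summed effective length and by the fragments of the library. The effective length of a locus came from the FPKM per fragment found at its length in each library. Long loci implied mean fragment lengths of 162, 163 and 167 bp for the 3 libraries. This main value departs from the fixed design. The sum as first planned is given as an alternative beside the counts of genes higher or lower in each comparison. The size rule was kept, namely a difference of at least 1 in log2(FPKM + 1), a pseudocount of 1 and a mean FPKM of at least 1 over the 3 libraries, which left 9555 of 13651 measured entries. With 1 deposited table per salinity, treated as 1 library, no test and no p-value was computed. Counting intervals are 95% intervals for a ratio of Poisson counts, and they cover counting error only, since fragments copied by PCR are not independent. A gene at 0 was set against a floor of 3 counts per library.

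Gene lists held 519 symbols, of which 437 were matched to entry names, and 8 symbols stood on more than 1 list. Of 26 lists, 25 had at least 5 measured members. The list of liver markers had 3 and was not tested. The tested lists were ion secretion, freshwater uptake, intestinal transport, divalent ions, aquaporins, tight junction, osmolytes, hormones, heat shock, oxidative stress, glycolysis, respiration, lipids, immune, cell cycle and proteasome genes. Markers were of erythrocytes, skeletal and smooth muscle, enterocytes, goblet cells, pancreas, kidney, gill and leukocytes. A list median was ranked among 10000 random lists of the same size and matched mean expression, and called outside when below the 2.5th or above the 97.5th percentile. Its interval came from 2000 bootstrap draws over members. Named genes were the 10 highest and 10 lowest differences with a mean FPKM of at least 10, up to 4 members per list with the largest difference, and 14 genes named in advance whatever their value. Values of a few genes that this rule or the lists hold are not reported here, though they stayed in the counts and list medians. Other genes in the text were chosen after their values were seen and are said to be so. Annotation terms of the files with 15 to 200 genes were ranked in the same way.

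The calculation was tested on simulated fragments of 9526 genes. For 25 against 0, the size rule called 20 of 66 genes changed 2-fold, 58 of 66 changed 4-fold, 60 of 62 changed 8-fold and 408 of 9332 unchanged genes. For 10 against 0 it called 360 of 9332 unchanged genes. Fragment totals were recovered at 100% in each simulated library. The simulated values were built with the same relation, so this checks the arithmetic and not the totals of the deposited tables. Alternatives planned in advance numbered 10, covering pseudocounts of 0.1 and 5, filters of none and 5, the highest row per gene, 3 rescalings, a size rule of 2 and every row counted. Another 6 were added after the data were seen, namely the sum of all rows, which had been planned as the main value, all loci weighted by length, loci of at least 300 bp, at least 30 fragments, a single effective length, and rescaling without haemoglobin and ribosomal protein genes. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.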

Results

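RNA of juvenile marbled eels (Anguilla marmorata), a fish that lives in fresh water and migrates to the sea to breed, was sequenced at salinities labelled 0, 10 and 25. Gill, kidney and intestine were named together as the tissue of each sample. There was 1 deposited table per salinity, treated here as 1 library, so no difference below had a replicate check and no p-value was computed. The labels' protocols speak of 9 libraries, and whether a table holds 1 library or a pool is not given in the sources used here. The deposited FPKM was scaled to totals of about 17600708 fragments at salinity 0, 18325768 at 10 and 16247643 at 25. The values of annotated genes rested on fewer fragments, 3957359 at salinity 0, 4375322 at 10 and 3598113 at 25. Values are FPKM per gene, and intervals are 95% counting intervals, which cover counting error only. A gene was counted as higher or lower when log2(FPKM + 1) differed by at least 1, among 9555 annotated genes with a mean of at least 1 FPKM. A difference on this scale understates that of low genes. Each list of genes was fixed before the data were examined, and its median was ranked among 10000 random lists of matched expression. The interval beside a list median is a 95% bootstrap over its members. Genes were named by a rule fixed in advance, with exceptions that were chosen after their values were seen. The exceptions were RHCG, APOB, SLC6A8, MKI67, CLDN10, ATP5B, OCLN, FABP3, FABP7, ALPI, APOA1 and the others said to be so.

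The comparison of salinity 25 with salinity 0 asked which transcripts differed between eels brought stepwise to the highest salinity and eels left in fresh water. ATP1B1, a beta subunit of the sodium pump, was measured at 172 FPKM at salinity 0 and 417 at 25, 2.43-fold (2.34 to 2.52) higher, and FXYD2, a small regulator of that pump, was 22.5-fold (20.8 to 24.4) higher. SLC12A1, the sodium-potassium-chloride cotransporter of absorptive epithelia, stood at 13 and 227 FPKM, 17.6-fold (12 to 26.8) higher. SLC12A3, the thiazide-sensitive sodium-chloride cotransporter, was 6.64-fold (4.21 to 11) lower, and AQP3, an aquaglyceroporin, was 19.1-fold (14.5 to 25.5) lower.

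Of the 25 tested lists, 11 lay outside the central 95% of random lists here. Of the 9555 genes, 666 were higher and 2818 lower at salinity 25, with a median difference of -0.50. After rescaling by median of ratios, which moved this comparison by 0.55, 1328 were higher and 1583 lower, so the share of higher among called genes went from 19.1% to 45.6%. With the deposited FPKM of all rows of a gene summed, the form first planned, the counts were 1404 and 5911. A simulation of counting error alone called 194 of 9332 unchanged genes higher and 214 lower. Median-of-ratios scaling moved 10 against 0 by 0.28 and 25 against 10 by 0.27. Rescaling to the same sum moved the comparisons by -0.15 for 10 against 0, -0.48 for 25 against 0 and -0.33 for 25 against 10. Leaving out the 50 highest genes moved 10 against 0 by 0.11 and 25 against 10 by -0.12. List medians are therefore read against the median of all genes.

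On the ion secretion list, the median was 0.72 (-1.90 to 1.68, percentile 99.7), with 4 of 8 members higher and 3 lower. KCNJ1, a potassium channel, went from 4.28 to 0.411 FPKM. This median was -0.39 when the highest row stood for each gene, -0.78 with all rows summed and -0.17 with all loci weighted by length. CFTR, the apical chloride channel, was low in all 3 libraries, at 1.62, 2.03 and 1.95 FPKM from 23, 30 and 23 fragments, and no difference was detectable at this depth. SLC12A2, the secretory cotransporter, had 1 to 2 fragments per library and no fold was computed. The freshwater uptake list had a median of -0.80 (percentile 5.89), with 1 of 17 members higher and 7 lower. SLC9A3, a sodium-proton exchanger, was 5.45-fold (3.88 to 7.84) lower, and the ammonia transporters RHBG and RHCG were 4.40-fold and 3.88-fold lower.

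The intestinal transport list had a median of 0.44 (-1.77 to 1.95, percentile 98.9), with 2 of 9 members higher and 2 lower. It was -0.57 with all rows summed, and its percentile was 96.9 after median-of-ratios scaling, 72.0 by the highest row, 96.6 with a pseudocount of 5 and 91.4 over loci of at least 300 bp. SLC26A6, a chloride-bicarbonate exchanger, was 4.09-fold (3.17 to 5.33) higher and SLC4A2 was 7.78-fold (6.72 to 9.05) lower. The divalent ion and sulfate list had a median of -0.80 (percentile 30.1), with 0 of 8 members higher and 3 lower. Of the lower members, CNNM4 rested on 3 and 0 fragments and STC2 on 2 and 0. SLC26A1, a sulfate transporter, was 82.1 FPKM at salinity 0 and 4.37 at 25. The aquaporin list had a median of 0.50 (percentile 95.1), with 2 of 5 members higher and 2 lower. AQP8 was 18.5-fold (13.4 to 26.5) higher and AQP1 2.51-fold (2.21 to 2.86) higher, opposite to AQP3.

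Tight junction genes had a median of -1.18 (-2.00 to -0.70, percentile 0.245), with 12 of 17 members lower and 1 higher. Occludin (OCLN) was 3.02-fold (2.70 to 3.37) lower and CLDN5 5.69-fold (4.87 to 6.67) lower, and CLDN10, a claudin that forms ion pores, was the higher member, at 3.76-fold (3.39 to 4.17). CLDN18 was at least 96.5-fold lower, against a floor of 3 counts per library. The osmolyte list had a median of 0.46 (-0.16 to 0.93, percentile 99.9), with 5 of 20 members higher and 4 lower, though the median was -0.88 with all rows summed and -0.07 with all loci weighted. CHDH, which makes the osmolyte betaine from choline, was 11.6-fold (7.15 to 20) higher, and the creatine transporter SLC6A8 was 2.34-fold (2.20 to 2.5) higher. SLC6A6, the taurine transporter, was 2.29-fold (2.03 to 2.59) higher, a difference of 1.11 that was -1.96 with all rows summed and -11.41 when the highest row stood for the gene. NFAT5, an osmotic stress transcription factor, stood at 11.6 and 5.01 FPKM, a difference of -1.06 that was 1.10 by its highest row, and TSC22D3 at 333 and 524. The hormone and receptor list had a median of -0.10 (percentile 84.7), with 3 of 15 members higher and 4 lower. The natriuretic peptide receptor NPR3 was 7.75-fold (6.16 to 9.85) lower. The prolactin receptor PRLR stood at 17.4 and 14.9 FPKM and the glucocorticoid receptor NR3C1 at 16.1 and 15.8.

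Mitochondrial respiration genes had a median of 0.81 (-0.15 to 1.16, percentile 100), with 13 of 29 members higher and 5 lower. The ATP synthase subunits ATP5A1 and ATP5B were 2.82-fold and 2.66-fold higher, whereas the adenine nucleotide carrier SLC25A4 went from 12.7 to 1.29 FPKM. Cell cycle genes had a median of -1.49 (-1.70 to -1.15, percentile 0), with 17 of 21 members lower and 0 higher. MKI67, a marker of dividing cells, was 7.79-fold (6.01 to 10.3) lower, and PCNA was 6.39-fold (4.38 to 9.64) lower. Immune genes had a median of -0.96 (-1.59 to -0.81, percentile 0.83), with 9 of 20 members lower and 0 higher. MX1, an antiviral GTPase, was 7.28-fold (3.79 to 15.7) lower. The cell cycle, tight junction and immune lists lay inside the central 95% when the highest row stood for each gene, at percentiles 7.52, 6.64 and 25.3. With all rows summed the tight junction and immune lists were at percentiles 12.1 and 9.74, and over loci of at least 300 bp the immune list was at 4.02.

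The lists of heat shock and oxidative stress genes lay inside the central 95%, with medians of -0.69 (percentile 4.11, 8 of 22 lower) and -0.72 (percentile 3.86, 5 of 22 higher and 8 lower). GPX4, which reduces lipid peroxides, was 14.3-fold (13.3 to 15.3) higher, while HMOX1 was 8.46-fold (5.55 to 13.5) lower. HSPA8, a constitutive chaperone, stood at 36.2 and 21.8 FPKM. Glycolysis genes had a median of -0.13 (percentile 68.8), with ENO3 5.97-fold (5.56 to 6.42) higher. Ubiquitin and proteasome genes had a median of -0.33 (percentile 21.3), with 1 of 18 members higher and 2 lower. Lipid genes had a median of -0.17 and a mean of 0.44, of opposite sign (percentile 93.0), with 8 of 25 members higher and 5 lower. FABP1, a fatty acid carrier of intestine and liver, stood at 58.4 and 4075 FPKM, 69.8-fold (48.1 to 105) higher, and APOB, the lipoprotein backbone, was 8.84-fold (8.42 to 9.29) higher.

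Markers of tissues also differed between these libraries. Enterocyte markers had a median of 1.86 (0.73 to 2.90, percentile 100), with 9 of 13 members higher and 0 lower. Of the 13, 9 had at least 30 fragments over the 3 libraries. Among the higher, APOA4 rested on 0 and 9 fragments, MTTP on 2 and 8 and ALPI on 0 and 5. MEP1A, a brush border protease, was 28.0-fold (19.5 to 41.5) higher, and FABP2 was 7.58-fold (6.83 to 8.43) higher by all its loci, a difference of 2.90, but -0.43 over loci of at least 300 bp alone. Exocrine pancreas markers had a median of 1.57 (percentile 99.9), erythrocyte markers -2.10 (percentile 0.06) and skeletal muscle markers -1.25 (percentile 0.39). By the highest row the erythrocyte and skeletal muscle lists were inside the central 95%, at percentiles 5.48 and 9.32, and with all rows summed skeletal muscle was at 6.90. Gill markers had a median of -0.93 (percentile 4.56), kidney markers -0.65 (percentile 28.5), smooth muscle markers -1.13 (percentile 3.50) and leukocyte markers -0.97 (percentile 6.03). Goblet cell markers had a median of -0.34 and a mean of 0.01 (percentile 58.3). The enterocyte median stood beside the higher SLC12A1, AQP8, FABP1 and APOB, and the gill median beside the lower RHBG, RHCG and AQP3. Not all lipid carriers were higher, with FABP3 at -1.60 and FABP7 at -1.31, and the lipid list lay inside the central 95%. Stomach genes, examined after the values were seen, were measured almost only at salinity 0. Pepsinogen A (PGA) stood at 4277 FPKM at 0, 5.35 at 10 and 0 at 25, and the proton pump ATP4A at 459, 0 and 0.

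**Figure D1:**
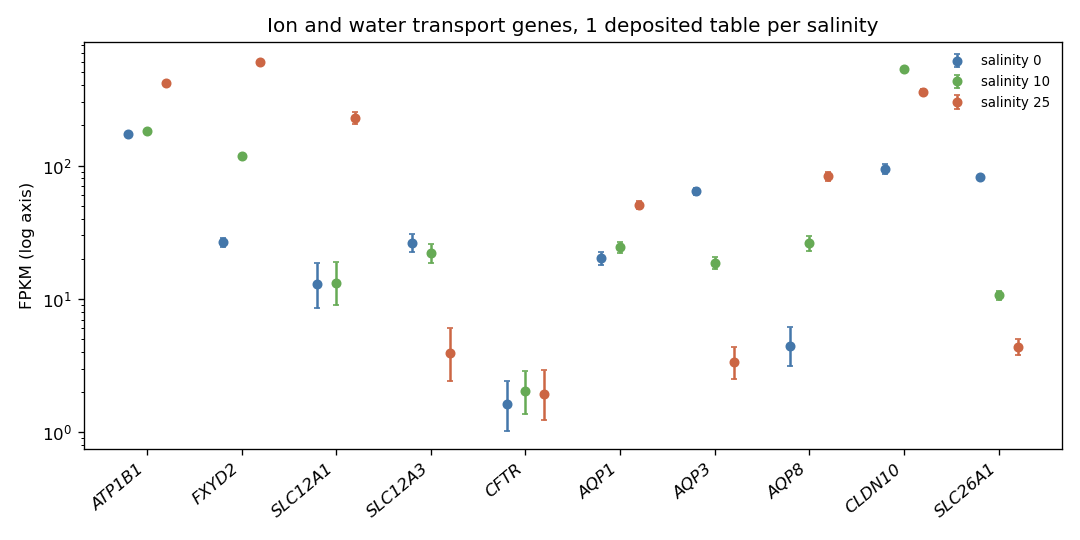
FPKM on a log axis of ion and water transport genes at salinities 0, 10 and 25, with 1 deposited table per salinity; bars are 95% counting intervals. FXYD2 stood at 26.6, 118 and 599 FPKM and AQP3 at 64.2, 18.6 and 3.36, whereas CFTR lay between 1.62 and 2.03. Values pool all gene models of a name, so levels of different genes are not directly comparable.

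Coordinates are those of the deposited tables, whose genome build is not given in the sources used here. Each row of the tables is a locus of about exon size, and whether it is coding or untranslated is not given. Several genes were annotated to more than 1 gene model, and these models, examined after the values were seen, did not always move together. SLC12A1 fragments came mostly (91.8%) from model g5372 on scaffold404 at 165340 to 181825, which stood at 5.08, 17.0 and 410.2 FPKM at salinities 0, 10 and 25, whereas its other model, g584, stood at 22.5, 8.77 and 5.45. SLC12A3 was led by g13374 on scaffold2090 at 33449 to 57275, with 28.0, 21.98 and 0.951 FPKM, and its other model g10621 stood at 20.2, 21.7 and 14.98. ATP1B1 lay on scaffold225 at 252266 to 270613 and FXYD2 on scaffold4004 at 38250 to 46865, each as 1 model. AQP1 lay mainly on scaffold7 at 239074 to 241567, AQP3 on scaffold2495 at 30118 to 35565, AQP8 mainly (94.4%) on scaffold126 at 314216 to 324682 and CFTR on scaffold13750 at 736 to 18038. The other AQP8 model, g38180, stood at 7.15, 0.888 and 3.67 FPKM from 31, 4 and 14 fragments, lower at 10 where the pooled value was higher. Paralogues that share an annotation were pooled, so a gene value may hold more than 1 copy. The length of models with few fragments also lowers such a value. The main AQP3 model, g14464, stood at 339, 98.2 and 17.5 FPKM and the main AQP1 model, g214, at 75.6, 91.3 and 192. Levels of different genes are therefore not directly comparable.

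The comparison of salinity 10 with salinity 0 asked which transcripts already differed at brackish salinity. ATP1B1 was at 1.06-fold (1.02 to 1.11) of its salinity 0 value, while FXYD2 was 4.42-fold (4.05 to 4.83) higher. SLC12A3 was at a ratio of 0.839-fold (0.668 to 1.05), so no difference was detectable at this depth. SLC12A1 was at a ratio of 1.02-fold (0.591 to 1.78) over all its loci, but its models moved in opposite ways, g5372 from 5.08 to 17.0 FPKM (6 and 21 fragments) and g584 from 22.5 to 8.77 (22 and 9 fragments). CLDN10 was 5.61-fold (5.09 to 6.20) higher and AQP8 5.85-fold (4.14 to 8.48) higher. AQP3 was 3.46-fold (3.07 to 3.91) lower, SLC9A3 3.71-fold (2.84 to 4.90) lower and SLC26A1 7.71-fold (7.09 to 8.39) lower. TSC22D3, a glucocorticoid-induced regulator, stood at 333 FPKM at 0 and 642 at 10.

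Of the 9555 genes, 310 were higher and 1467 lower at salinity 10, with a median difference of -0.20. Median-of-ratios scaling gave 453 and 958, so that the share of higher among called genes went from 17.4% to 32.1%. With all rows summed the counts were 1152 and 4349, and with at least 30 fragments per gene they were 198 and 867. A simulation of counting error alone called 189 of 9332 unchanged genes higher and 171 lower. Of the genes with the 10 largest differences, 10 of the higher and 6 of the lower rested on under 30 fragments, and they are not interpreted further.

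Among genes with at least 30 fragments, a filter chosen after the values were seen, contactin-2 (cntn2) was highest, at 2.89 FPKM at 0, 166 at 10 and 179.5 at 25. The ileal bile acid carrier FABP6 was 19.5-fold (10.4 to 41.3) higher and the tetraspanin-like t4s4 10.9-fold (8.18 to 14.8) higher. The folate receptor folr1 was 8.97-fold (5.51 to 15.5) higher and papilin (ppn1) 9.13-fold (7.82 to 10.7) higher. The lowest were stomach genes, with pepsinogen A (pepa) 799-fold (467 to 1501) lower and claudin CLDN18 at least 119-fold lower.

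Lists outside the central 95% of random lists numbered 6. Enterocyte markers had a median of 0.88 (0.00 to 1.28, percentile 100), with 5 of 13 members higher and 2 lower. The lower MEP1B went from 50.3 to 3.54 FPKM, from 1434 and 105 fragments. The other lower member, APOA1, rested on 3 and 1 fragments, and the higher APOA4 on 0 and 2. Kidney markers had a median of 0.37 (-0.68 to 1.53, percentile 99.96), with 4 of 13 members higher and 2 lower. The interval held the median of all genes, -0.20. The tubule protein uromodulin (UMOD) was 5.53-fold (4.67 to 6.59) higher and the amino acid transporter subunit SLC3A1 4.68-fold (3.59 to 6.19) higher. The kidney median was -0.13 with all loci weighted by length. Skeletal muscle markers had a median of 0.88 (0.30 to 2.53, percentile 100), with 7 of 15 members higher and 1 lower. Parvalbumin (PVALB) was 7.92-fold (7.04 to 8.94) higher and MYL1 15.4-fold (11.5 to 21.0) higher. Erythrocyte markers had a median of 0.70 (-0.13 to 1.25, percentile 99.9), with 2 of 7 members higher and 1 lower. The haemoglobin chain HBB stood at 8062 FPKM at 0, 29063 at 10 and 879 at 25. TFRC, the other higher member, differed by 1.25, but by -1.83 with all rows summed and -7.81 by its highest row. The lower SLC4A1 went from 46.0 to 22.1 FPKM. Exocrine pancreas markers had a median of -2.67 (-3.17 to -1.61, percentile 0), with 6 of 7 members lower. The intestinal transport list had a median of 0.51 (-0.52 to 0.98, percentile 99.9), which was -0.27 by the highest row, -0.85 with all rows summed and -0.20 over loci of at least 300 bp. The pancreas list was at percentile 2.72 by the highest row and the kidney list at 97.1 with no filter, both inside the central 95%. The respiration median of 0.13 and mean of -0.08 differed in sign (percentile 89.4). The other tested lists lay inside the central 95%, with cell cycle at -0.25 (percentile 44.4) and tight junction at -0.09 (percentile 54.6).

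**Figure D2:**
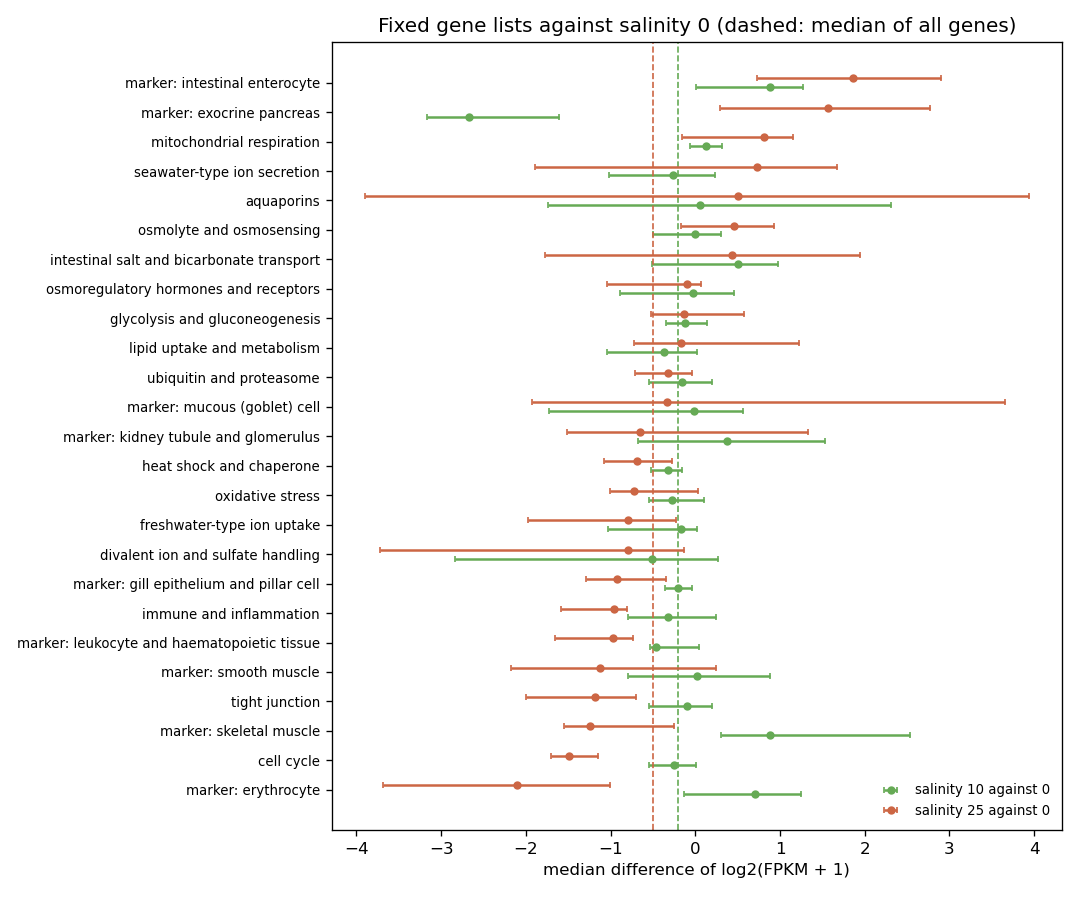
Median difference of log2(FPKM + 1) of each fixed gene list at salinity 10 and at salinity 25 against salinity 0, with 1 deposited table per salinity; bars are 95% bootstrap intervals over list members, and dashed lines mark the medians of all genes, -0.20 and -0.50. Enterocyte markers stand at 0.88 and 1.86, exocrine pancreas markers at -2.67 and 1.57 and cell cycle genes at -0.25 and -1.49.

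The comparison of salinity 25 with salinity 10 asked what differed between the higher and the intermediate salinity. Most of the SLC12A1 difference lay here, 17.2-fold (11.8 to 25.8) higher at 25, as did that of ATP1B1, 2.28-fold (2.21 to 2.37) higher. SLC12A3 was 5.58-fold (3.52 to 9.28) lower and AQP3 5.52-fold (4.13 to 7.49) lower. CLDN10 was 1.49-fold (1.40 to 1.59) lower than at 10, and FXYD2 was 5.09-fold (4.89 to 5.30) higher. GPX4 was 11.2-fold (10.5 to 11.9) higher and FABP1 514-fold (200.3 to 1889) higher.

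Of the 9555 genes, 731 were higher and 1377 lower at 25, with a median difference of -0.21. Median-of-ratios scaling gave 1132 and 1000, so that the share of higher among called genes went from 34.7% to 53.1%. With all rows summed the counts were 2114 and 3491, and with at least 30 fragments 517 and 1029.

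Of the 25 tested lists, 14 lay outside the central 95% here. Respiration genes had a median of 0.67 (0.25 to 1.00, percentile 99.9), with 9 of 29 members higher and 1 lower. Cell cycle genes had a median of -1.06 (-1.62 to -0.95, percentile 0.02), with 14 of 21 members lower, among them PCNA, 7.67-fold (5.28 to 11.5) lower. Tight junction genes had a median of -0.79 (percentile 0.45) and immune genes -0.80 (percentile 0.17), with 7 of 17 and 7 of 20 members lower. By the highest row cell cycle, tight junction and immune genes were inside the central 95%, at percentiles 6.19, 19.5 and 5.41, and tight junction was at 15.4 with all rows summed. The ion secretion median was 0.57 (percentile 98.4), but -0.10 over loci of at least 300 bp, and its percentile was 82.7 with all rows summed. The osmolyte median was 0.36 (percentile 98.4), with SLC6A6 3.74-fold (3.24 to 4.32) higher, and was -0.07 with all rows summed and -0.11 with all loci weighted. SLC6A6 itself was at -0.83 with all rows summed and -10.31 by its highest row. The hormone list median was 0.56 (percentile 99.9), but -0.05 with no filter on low values and -0.06 over loci of at least 300 bp. The divalent ion list median was -1.02 (percentile 0.56), but 0.00 with no filter and -0.14 with all loci weighted, both above the median of all genes there.

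Exocrine pancreas markers had a median of 3.24 (2.09 to 5.70, percentile 100), with the elastase CELA2A 144-fold (101.3 to 212) higher and trypsin PRSS1 58.7-fold (36.9 to 99.5) higher. Enterocyte markers had a median of 1.68 (percentile 100), with 10 of 13 members higher and 1 lower. Among the higher, APOA1 rested on 1 and 3 fragments at 10 and 25, APOA4 on 2 and 9 and MTTP on 0 and 8. Erythrocyte markers had a median of -2.25 (percentile 0.01), skeletal muscle markers -1.25 (percentile 0.02) and smooth muscle markers -1.27 (percentile 0.35). HBB was 33.1-fold (30.9 to 35.4) lower and ALAS2, the first enzyme of haem synthesis in red cells, 38.6-fold (26.4 to 58.9) lower. Gill markers had a median of -0.87 (percentile 1.02), beside kidney markers at -0.60 (percentile 4.34). Skeletal muscle was at percentile 19.1 over loci of at least 300 bp. By the highest row and with all rows summed, smooth muscle was at 13.9 and 8.60 and gill at 17.9 and 11.7. The respiration, enterocyte, pancreas and erythrocyte lists stayed outside in each setting that gave them a value. Medians and means differed in sign for aquaporins (0.45 and -0.01), oxidative stress (-0.25 and 0.06), goblet cell markers (-0.20 and 0.30) and ubiquitin and proteasome genes (0.08 and -0.09).

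Across the 3 salinities, 146 genes were higher at both 10 and 25 than at 0 and 1091 were lower at both. FXYD2 and AQP8 were higher at both, and AQP3 and SLC26A1 were lower at both. Another 135 genes were higher at 10 alone and 491 at 25 alone, with GPX4 in the latter. Lower at 10 alone were 347 genes and at 25 alone 1698, among them SLC12A3, OCLN and MKI67. A further 58 genes were past the rule in opposite directions, among them PVALB and UMOD. Both comparisons shared the salinity 0 library, so chance values were set beside these counts. Independent lists of the same sizes would share 21.6 higher and 433 lower genes. Simulated unchanged groups under the size rule, the form fixed in advance, shared 554 and 550, so 146 lay below and 1091 above. The data had median differences of -0.20 and -0.50 over all genes, a shift the simulation lacked. Such a shift lowers the first count and raises the second, so this form cannot tell shared differences from scaling. With as many genes called as in the data, a form chosen after the counts were seen, the simulated groups shared 129 and 895. The correlation of the differences across genes, which are not independent replicates, was 0.56, where a shared library alone gives 0.50 at equal spreads. Their covariance was 0.62 against 0.53 simulated, and the simulated spread, taken from 25 against 10, holds any difference between those libraries. Median-of-ratios scaling gave 243 higher and 568 lower at both, and summing all rows gave 419, 3150 and 437 in opposite directions.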

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

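The tests of the stomach, enterocyte and pancreas patterns were all chosen after the results they bear on had been seen. Gene models without a protein entry name, which no comparison of the report uses, also gave signal. Of these models 9879 entered the count, fewer than all without a name, and 1426 of them were measured. Measured models at least 2-fold higher than at 0 numbered 56 at salinity 10 and 100 at salinity 25. Those at least 2-fold lower numbered 180 and 434. The files do not pair them with gene names. Models g20273 (59.8 FPKM at 0 and 240.0 at 10) and g24360 (5.14 at 0 and 59.4 at 25) are examples with at least 1000 fragments. Annotated genes with at least 30 fragments, each pooling all models of an entry name, are set beside these models. Among them 2.47% were higher at 10 and 6.75% at 25, beside 3.93% and 7.01% of the models here. The shares lower were 10.83% and 25.82%, beside 12.62% and 30.43%. In a simulation of unchanged annotated genes, counting error alone called 2.03% higher and 1.83% lower for 10 against 0. For 25 against 0 it called 2.08% and 2.29%. The simulation had no fragment minimum, so its rates are not those of genes with at least 30 fragments.

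Stomach genes were seen almost only at salinity 0, with gastricsin (PGC) at 1757, 0.987 and 0 FPKM and the junction protein CLDN18 at 98.1, 0 and 0. The upper counting limit of the summed junction and pump genes CLDN18, VSIG1, ATP4A and ATP4B at salinity 25 was 6.95% of their level at 0. CLDN18 and VSIG1 were among the genes that prompted the pattern, so a low sum was likely from the start. It cannot decide whether stomach cells stayed in all 3 libraries with only secreted enzymes lower. That stomach tissue entered the salinity 0 library alone may be the cause, but of 3 further stomach genes 2, ATP4A and ATP4B, were at least 4-fold lower in both other libraries. These are too few to decide, SOX2 stood at 3.93, 1.41 and 0.658, and both pump genes were themselves among the lowest differences, so they add little. A loss of stomach gene expression with salinity stays open as untested.

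Enterocyte markers were higher at salinity 25, with a median at percentile 100 of random lists, the value that prompted the pattern. A larger share of intestine in that library may be the cause but was not decided, since the bootstrap intervals of the gill (-1.29 to -0.34) and kidney medians (-1.52 to 1.33) both held the median of all genes, -0.50. Whether that share is the whole rise of SLC12A1 was not decided, since all its loci lay 1.16 SD above the enterocyte list mean, within the bound of 2 SD, but its main model g5372 lay 2.35 SD above, or 1.69 at its counting limits. AQP3 lay at -2.67 SD from the gill list mean, and its main model at -2.93 or -2.54 at its counting limits, past the bound of 2 SD. That cannot decide whether a smaller share of gill was its whole cause, since most gill-list genes, such as keratins, are also expressed in other epithelia. A response of the same cells to salinity was not separated from a change in the tissue mixture.

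Pancreatic enzyme genes differed between all 3 libraries. Of 7 measured pancreas-list genes, 6 by FPKM were at least 4-fold lower at 10 than at 0 and at least 4-fold higher at 25 than at 10, and 5 differed by at least 2 both times in log2(FPKM + 1). Uneven carry-over of pancreas may be the cause. The 6 met the share set for it after the values were seen, while the 5, on the scale counted first, did not. CEL among the 6 rested on 1 fragment at salinity 10. These genes also prompted the pattern, so the count cannot decide. A single shift in intestine share that moved both lists together was examined through the pancreas median of -2.67 at 10 against 0, beside an enterocyte median of 0.88, which went the opposite way but did not pass the bound of 1. A response of pancreatic genes to salinity stays open as untested.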

How the results depend on the processing

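Results at other settings were compared with the values given for each comparison. Of 1014 list medians recomputed, 957 stayed inside the bootstrap interval of the value given, 52 moved outside it and 5 reversed, each taken relative to the median of all genes. Of 5585 values of named genes, 5159 kept direction and side of the size rule, 108 passed it newly, 265 no longer passed and 53 reversed. Settings that sum rows, take the highest row, weight all loci or use loci of at least 300 bp were those with reversed genes. Weighting all loci and loci of at least 300 bp were chosen after the data were seen, and so was the use of the sum, the form first planned, as an alternative. The filters of 5 FPKM, 30 fragments and 300 bp test fewer genes by construction, and the size rule of 2 and the count of every row were run for counts only. Annotation terms had no alternative. No paired analysis was possible because each salinity had 1 library and no test was made, and for the same reason no library could be left out. Short loci limit depth, since 1 fragment in a locus of 110 bp is worth 136 FPKM at salinity 0. Beyond these constructions, the cause was not tested. The values that moved or turned are counts of genes or differences of log2(FPKM + 1).

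A pseudocount of 0.1 gave 2119 lower for 25 against 10. It left 91 opposite. A pseudocount of 5 gave 162 higher and 562 lower for 10 against 0, 437 higher and 1103 lower for 25 against 0 and 426 higher and 523 lower for 25 against 10. It left 62 higher at both salinities, 389 lower at both and 27 opposite. With no filter the divalent ion median for 25 against 10 became 0.00. A filter of 5 FPKM gave 731 lower for 10 against 0, 1401 lower for 25 against 0 and 868 lower for 25 against 10. Genes across salinities were then 521 lower at both. The highest row per gene gave 1571 higher and 4172 lower for 10 against 0, 1999 higher and 5140 lower for 25 against 0 and 2552 higher and 3347 lower for 25 against 10. Genes across salinities were then 576 higher at both salinities, 3064 lower at both and 314 opposite. Lists outside the central 95% numbered 4 for 25 against 0 and 8 for 25 against 10. The intestinal transport median for 10 against 0 became -0.27. For 10 against 0 the sign turned for chs2 -1.08, SLC34A2 -0.059, DNAJC3 8.44, GCLM 0.93, HMOX1 0.066, PCK2 0.49, RRM2 0.26, PSMD1 10.31, TFRC -7.81 and SLC22A6 -0.18. Against 0, at 25 it turned for CCND1 0.46, ACTA2 0.11, PPL 0.44, SLC6A6 -11.41 and NFAT5 1.10. For 25 against 10 the sign turned for SLC6A6 -10.31, HSPA1A 0.28, HSP90AB1 1.41 and NFAT5 2.66. Median-of-ratios scaling gave 958 lower for 10 against 0, 1328 higher and 1583 lower for 25 against 0 and 1132 higher for 25 against 10. It left 243 higher at both salinities and 568 lower at both. Rescaling to the same sum gave 352 higher and 4343 lower for 25 against 0 and 445 higher and 2140 lower for 25 against 10. A size rule of 2 gave 92 higher and 304 lower for 10 against 0, 182 higher and 703 lower for 25 against 0 and 163 higher and 282 lower for 25 against 10. Counting every row gave 8140 higher and 29220 lower for 10 against 0, 8893 higher and 37659 lower for 25 against 0 and 13272 higher and 22077 lower for 25 against 10. Summing all rows gave 1152 higher and 4349 lower for 10 against 0, 1404 higher and 5911 lower for 25 against 0 and 2114 higher and 3491 lower for 25 against 10. Genes across salinities were then 419 higher at both salinities, 3150 lower at both and 437 opposite. Lists outside the central 95% numbered 6 for 25 against 0 and 9 for 25 against 10. The intestinal transport median for 10 against 0 became -0.85. For 10 against 0 the sign turned for GCLM 0.10, PSMD1 0.90 and TFRC -1.83. Against 0, at 25 it turned for SLC6A6 -1.96. For 25 against 10 the sign turned for OCLN 0.79 and SLC6A6 -0.83. Weighting all loci by length gave 548 higher for 10 against 0, 1096 higher for 25 against 0 and 1223 higher for 25 against 10. It left 236 higher at both salinities and 113 opposite. The divalent ion median for 25 against 10 became -0.14. For 10 against 0 the sign turned for plin3 0.38, zn511 -0.36, d42e1 -0.33, igg2b -0.84, CLDN12 0.11, HMOX1 0.017, PCK2 0.25, TFRC -0.21 and SLC22A6 -0.13. Against 0, at 25 it turned for sf3b5 -0.54, DNAJA1 0.50 and ACTA2 0.030. For 25 against 10 the sign turned for cas1 6.63, ube2t 3.27, cckn 1.24, nop16 -0.57, sf3b5 -0.35, plin3 -0.26, CNNM4 0.035, DNAJA1 1.31, CCND1 0.48 and BUB1 0.16. Using loci of at least 300 bp gave 170 higher and 439 lower for 10 against 0, 362 higher and 1281 lower for 25 against 0 and 304 higher and 795 lower for 25 against 10. It left 73 higher at both salinities, 356 lower at both and 22 opposite. Lists outside the central 95% numbered 7 for 25 against 10. The intestinal transport median for 10 against 0 became -0.20. For 10 against 0 the sign turned for chia 0.094 and BHMT 0.053. Against 0, at 25 it turned for BHMT 0.84 and FABP2 -0.43. For 25 against 10 the sign turned for mrc1l 0.48 and FABP2 -0.22. Requiring 30 fragments gave 198 higher and 867 lower for 10 against 0. Genes across salinities were then 94 higher at both salinities and 673 lower at both.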

Other observations

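The genes named in this part were chosen after their values were seen. The beta-type sodium pump subunit annotated as at233 stood at 368 FPKM at 0, 609 at 10 and 1728 at 25. The type-4 ice-structuring protein afp4 was at 1178, 881 and 19804 FPKM, and apolipoprotein A-I (apa11) at 77.5, 181 and 1702. The intestinal phosphodiesterase enpp7 was 35.3-fold (27.5 to 46.2) higher at 25 than at 0. The galactoside-binding lectin leg was 12.4-fold (10.4 to 14.9) higher over all its loci, led by model g13708 at 12.8, 82.3 and 252.6 FPKM, while model g14513 stood at 17.1, 18.1 and 3.85.

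Genes with their highest level at 10 included foxq1, at 28.3, 130.0 and 11.9 FPKM, and UMOD, at 10.7, 59.4 and 3.10. The matrix protease mmp9 was at 85.1, 3.16 and 0 FPKM and s100p at 3177, 102 and 6.07, the last from 1 fragment.

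Of 1033 annotation terms, 13 lay below the 1st and 39 above the 99th percentile at 10 against 0, where chance gives 1% at each end. For 25 against 0 the numbers were 64 and 34 and for 25 against 10 they were 98 and 30. For 10 against 0 the lowest medians belonged to response to nicotine (-0.91), biosynthetic process (-0.87), early to late endosome transport (-0.78), endothelial cell migration (-0.75) and fructose metabolism (-0.73). The highest were mRNA metabolism (0.22), force of heart contraction (0.23), eye development (0.23), SMAD signal transduction (0.32) and bile acid metabolism (0.44). For 25 against 0 the lowest were cytoplasmic microtubule organization (-1.36), gut development (-1.35), early to late endosome transport (-1.34), calcium-independent cell adhesion (-1.31) and regulation of pH (-1.30). The highest were leucine catabolism (0.43), proton transport (0.68), translational elongation (0.77), ubiquinone biosynthesis (0.86) and mitochondrial electron transport from NADH to ubiquinone (1.02). For 25 against 10 the lowest were trophectodermal differentiation (-1.11), cardiac myofibril assembly (-1.10), regulation of striated muscle contraction (-0.97), negative regulation of neurogenesis (-0.94) and platelet activation (-0.90). The highest were translational elongation (0.54), benzoate metabolism (0.55), proton transport (0.59), ubiquinone biosynthesis (0.77) and electron transport from NADH to ubiquinone (0.79).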
